A study of Mus musculus with 4 samples.

How the data were processed

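Placentas of ICR mice, an outbred stock, were collected after transfer of frozen embryos or of fresh embryos, and total RNA of 4 placentas, 2 per group, was sequenced. Groups and replicate numbers came from the sample labels. The labels do not say whether the 2 placentas of a group came from separate recipients, so the p-values of single genes measure the spread between these samples.

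Per the labels' protocols, RNA was extracted with Trizol, reads were filtered with SOAPnuke 1.5.2 and mapped with HISAT2 2.0.4 to the sequencing company's reference gene set, lncRNA and mRNA were identified with Bowtie2 2.2.5, and RSEM 1.2.12 gave FPKM values. The values deposited by the authors are FPKM, fragment numbers scaled by transcript length and library total, with one value per gene with 2 decimals. FPKM are not counts, so no count test was run. The depth behind the FPKM values is unknown, and no counting interval is given. Positions are those of GRCm38, the build of the chromosome accessions in the deposited tables. Whether the library kit marked strand is not given in the sources used here, so antisense and overlapping genes are uncertain.

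Each table held 48549 features. Of these, 35558 were genes in FPKM and 12991 were circular RNAs. The circular RNA values in the same column are not FPKM: 99.99% or more of them in each library lay within 0.0015 of a whole multiple of a single step per library (0.118 to 0.162), as read counts scaled by library total (RPM) would. What total they refer to is not given in the sources used here. They were kept out of every FPKM test. From data row 33457 on, the annotation columns of all 4 tables (gene type and those to its right) were shifted down by 1 row against identifier, symbol and value. Of the genes with an Entrez number found in the RefSeq table of GRCm38.p6, 68.6% overlapped their RefSeq position as printed and 99.2% after the columns were moved back. The corrected columns were used. As printed, 2016 of the 14573 genes called lncRNA (13.8%) were mRNA genes once realigned. After realignment 15885 genes were lncRNA and 19673 were mRNA, as the files class them. Of the 27798 Entrez numbers, 27070 were matched in the RefSeq table, which also restored 26 symbols that had been turned into dates. A further 7550 lncRNA genes carry only an identifier of the sequencing company.

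Genes with a mean of at least 0.5 FPKM over the 4 libraries were tested on log2(FPKM + 1) with limma-trend (limma 3.58.1, R 4.3.3), frozen against fresh, two-sided, with Benjamini-Hochberg adjustment at 0.05. Fold changes are therefore on the log2(FPKM + 1) scale, which understates changes of low genes. For lncRNA genes the adjustment was made over lncRNA genes, as planned. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, for 45 of 50 lists with at least 5 genes tested, and beside it with an estimated correlation and with fry. At the preset correlation camera compares genes inside a list with genes outside and takes its degrees of freedom from genes. Its p-values there do not measure the spread between placentas. With an estimated correlation the degrees of freedom come from the samples, so the versions differ in more than the correlation. The estimated correlation was -0.060 for uterine natural killer cells and 0.338 for the prolactin family, and both calls were lost. With 2 samples against 2, an exact permutation test of 1 value cannot go below 0.333, so none was used, and groups of 2 do not overlap by chance in 33.3% of genes. Simulated libraries with the spread of the real ones (10 runs, 16929 genes) held, over all runs, 670 genes changed by a log2 value of 1, 670 by 2 and 660 by 3. Of these, 43.1%, 90.9% and 98.5% were called, and 0.0448% of unchanged genes. The shares called depend on how many genes change. In these runs camera called 0 of the 45 lists. This simulation drew genes independently and so says nothing of correlated genes. It does not show that large changes are absent from the real data. There, Rpl26 at a log2 fold change of 3.33 and Hsd11b1 at 2.11 did not pass in limma-trend (adjusted p = 0.121 and 0.146). Other computations used Python 3.11.15 with pandas 2.3.3, and plots used matplotlib 3.10.9.

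The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest changes per direction among genes with an adjusted p under 0.05, a mean of at least 1 FPKM in a group and libraries of the groups that did not overlap. Where fewer than 10 passed, it filled up to 5 per direction by the smallest unadjusted p among genes meeting the other conditions. It did the same for lncRNA genes (5 per direction), added up to 4 members of each list by smallest p, and 14 imprinted or X-inactivation genes. At most 2 features without a gene symbol were named per direction. The genes Gm4737, Gm15772, Tmem41b, Il2rb, Prl7b1, Prl3b1, Psg17, Cirbp, Acta2, Tpbpa, Tpbpb, Gzma, Gzmb, Gzmc, Prl8a2, Prf1, Ddx3y, BGIG10090_40680, Hbb-b1, Hbb-b2, Gm12191, Prl2c1 and Afp are named beside these and were chosen after their values were seen, where the rule does not name them. The planned test for counts was not used because the files held FPKM only. Members of a list were also adjusted by Benjamini-Hochberg over that list alone. This step was not among the planned tests and makes no allowance for the number of lists. The alternatives were median-of-ratios scaling, a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, leaving out each library, a replicate block, and leaving out X-inactivation, Y-linked, globin and mitochondrial genes. In the last of these each library was also rescaled to the same summed FPKM, which the main fit did not do. Upper-quartile scaling of FPKM, 2 other definitions of lncRNA and adjustment of lncRNA genes over all genes were added after the data were seen, as were upper-quartile scaling and the other pseudocount for the lists.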

Results

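The transcriptome of mouse placenta was compared between pregnancies from frozen embryo transfer, in which embryos are frozen and thawed before they are placed in a recipient, and from fresh embryo transfer. The question was which mRNA and lncRNA genes of the placenta differ between the 2 kinds of transfer. Each group had 2 placentas. Between 16662 and 17085 genes reached 0.5 FPKM in a library, and lncRNA genes held 21.2 to 21.8% of the summed FPKM. The summed FPKM was 461002 to 518538 per library, and the feature with the highest value in each of them, BGIG10090_40680 on chromosome 12, which the files class as lncRNA, held 13.8 to 14.8% of it. Sequencing depth is unknown from FPKM. The libraries correlated at 0.984 within each group and at 0.974 to 0.979 between groups across 16929 genes. The first principal component held 49.6% of the variance and placed both frozen libraries on one side and both fresh libraries on the other. One placenta was male and the other 3 were female: Xist was 7.40 FPKM in frozen replicate 1 and 87.6 to 101 FPKM in the others, and the Y-linked gene Ddx3y was 10.6 FPKM in frozen replicate 1 and listed at 0 in the others. Fetal sex was therefore not balanced, and the fit without frozen replicate 1 compares female placentas only.

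Eppk1 and the granzyme genes Gzmd and Gzmg were lower, and Epb41l4a, Atrnl1 and Ogn were higher, in both frozen placentas than in both fresh ones. No single gene passed the adjusted threshold over all genes. Among genes higher after frozen transfer, Epb41l4a, a protein of the band 4.1 family, was 12.2 ± 0.97 FPKM against 3.08 ± 0.23 (SD, n = 2), and the attractin-like receptor Atrnl1 was 66.6 ± 7.47 against 24.3 ± 2.14 FPKM. Ogn, which encodes the matrix proteoglycan osteoglycin, was 3.48 ± 0.35 against 0.47 ± 0.13 FPKM. Among genes lower after frozen transfer, Eppk1, which encodes the cytolinker epiplakin, was 13.4 ± 0.81 against 32.4 ± 0.071 FPKM, with a log2 fold change of -1.22 ± 0.095 (SE, adjusted p = 0.113). The granzyme gene Gzmg was 0.33 ± 0.27 against 7.20 ± 0.71 FPKM (adjusted p = 0.0989), and Gzmd was 0.37 ± 0.28 against 6.38 ± 0.014 FPKM. These genes were named by their unadjusted p and did not pass.

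Of 16929 genes tested with limma-trend, 0 had an adjusted p under 0.05, the smallest being 0.0954, and 2385 had an unadjusted p under 0.05, where 846 would be expected by chance. Of these 2385 genes, 1383 were higher and 1002 lower after frozen transfer. With upper-quartile scaling, added after the data were seen, 1074 were higher and 1303 lower, so the balance of directions depends on the scaling. The count at an unadjusted p under 0.05 was 1271 without frozen replicate 1 and 1414 without frozen replicate 2, and without frozen replicate 2 the adjusted count was 2, the globin copies Hbb-b1 and Hbb-b2, which were at 1894 and 432 FPKM in frozen replicate 1 and at most 0.13 FPKM elsewhere. Without sex-linked, globin and mitochondrial genes the adjusted count was also 2, the lncRNAs Gm2560 and BGIG10090_39217 (adjusted p = 0.0495, with a range of 0.0495 to 0.551 over the alternatives). The fit without sex-linked, globin and mitochondrial genes also rescaled each library to the same summed FPKM. Its calls can therefore not be credited to the genes left out alone. The libraries of the groups did not overlap for 47.8% of genes, against 33.3% by chance.

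**Figure D1:**
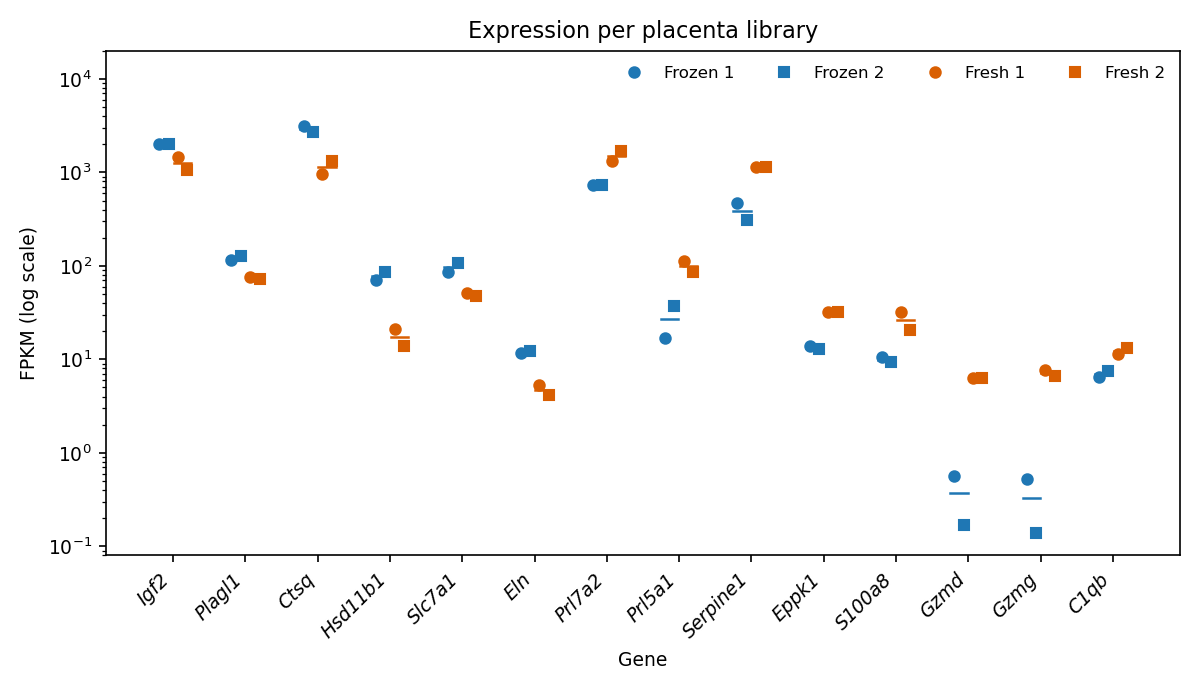
FPKM (log axis) of 14 genes named in the text in each of the 4 placenta libraries; points are single libraries and short lines are group means of 2. The frozen and fresh libraries do not overlap for these genes, as for Igf2 at 2034 and 1993 against 1463 and 1065 FPKM, and none of the genes passed the adjusted threshold over all genes.

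For 3 of the top features, a gene or pseudogene related by its annotation lies on another chromosome, and it differed in the opposite direction. Ahcy (chromosome 2, 155059310 to 155074497, GRCm38), which encodes adenosylhomocysteinase, was 4.35 ± 0.18 FPKM after frozen and 0.48 ± 0.057 FPKM after fresh transfer, while Gm4737 on chromosome 16, with which it shares an alias in RefSeq, was 7.82 and 7.74 against 11.6 and 10.2 FPKM. The sum of both was 12.3 and 11.96 against 12.1 and 10.6 FPKM. Rpl26, a protein of the large ribosomal subunit, was 180 and 106 FPKM after frozen and 15.6 and 10.5 FPKM after fresh transfer, and its transcribed pseudogene Gm15772 on chromosome 5 was 8.05 and 95.8 against 129 and 184 FPKM. Their sum was 188 and 202 against 144 and 194 FPKM. The lncRNA BGIG10090_39217 (chromosome 9, 90114887 to 90120749) overlaps a pseudogene of Tmem41b. It was 0.28 and 0.38 against 6.24 and 5.65 FPKM, while Tmem41b itself was 16.1 and 16.1 against 8.85 and 7.59 FPKM. RSEM divides reads between near-identical sequences, and the sequence identity of these pairs was not measured here.

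**Figure D2:**
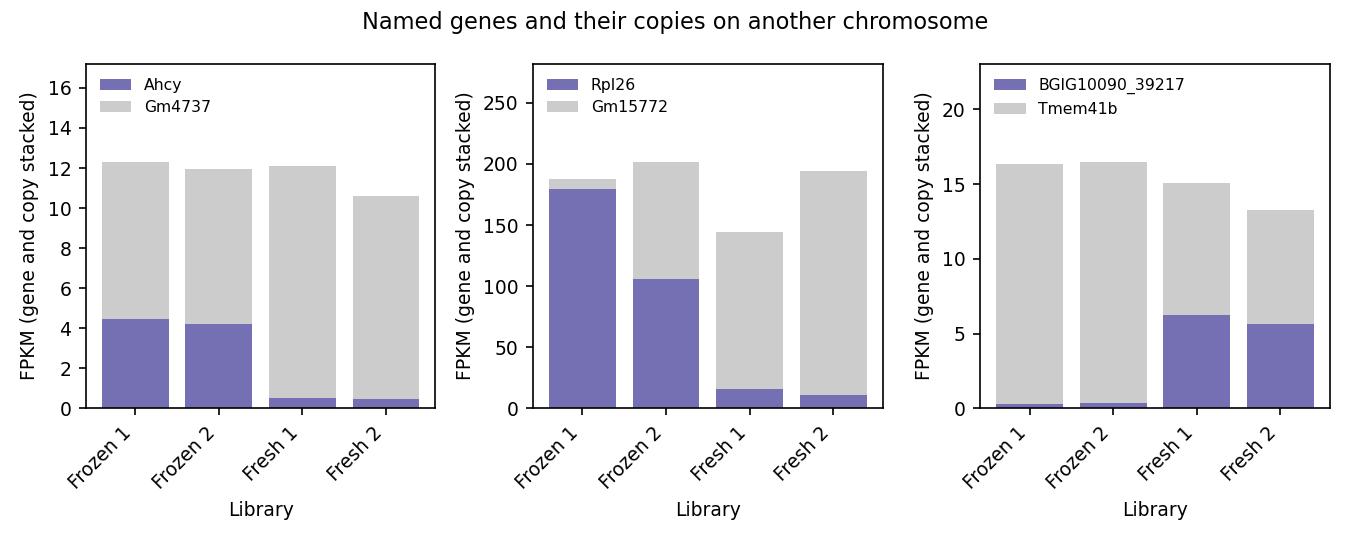
FPKM of 3 named features (purple) and of their copies on another chromosome (grey), stacked, in each library. The sum of Ahcy and Gm4737 lay between 10.6 and 12.3 FPKM in the 4 libraries while Ahcy alone lay between 0.44 and 4.48 FPKM.

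The lists of uterine natural killer cells, macrophages and neutrophils were lower on balance after frozen transfer, at the preset correlation of camera. No member of the lists described from here on passed over all genes in limma-trend, and members counted at an unadjusted p are given where 0 passed. Those counts are to be read against the 14.1% of all tested genes that had an unadjusted p under 0.05 in limma-trend. The list of uterine natural killer cells, the granule-bearing lymphocytes of the decidua, held 22 genes, of which 7 reached the minimum of 0.5 FPKM. All 7 were lower, 6 of them adjusted over the list alone and 0 over all genes, with a median log2 fold change of -1.67 (camera adjusted p = 1.96e-10, and adjusted p = 0.495 with an estimated correlation). Its top members were the neighbouring granzyme genes of chromosome 14: Gzmf was 0.34 ± 0.35 against 6.43 ± 1.00 FPKM and Gzme was 1.59 ± 0.45 against 7.19 ± 0.51 FPKM (SD, n = 2). Gzma, at 0.11 and 0.21 against 0.11 and 0.14 FPKM, and Gzmb, at 0.07 and 0 against 0.21 and 0.17 FPKM, were too low to test. The mean log2 fold change of this list was -1.63, and -0.59 with no filter and -2.63 with a pseudocount of 0.1, where it was still called. The interleukin-2 receptor chain gene Il2rb differed less, at 23.4 ± 0.25 against 28.5 ± 4.43 FPKM. Of 20 macrophage genes 17 were lower, 2 of them adjusted over the list alone, with a median of -0.35 (camera adjusted p = 8.81e-06, and adjusted p = 0.495 with an estimated correlation). The complement gene C1qb was 6.96 ± 0.72 against 12.2 ± 1.36 FPKM and Lyve1 was 4.14 ± 0.50 against 12.7 ± 5.10 FPKM. Of 8 neutrophil genes tested, from a list of 16, 7 were lower, 3 of them adjusted over the list alone (camera adjusted p = 0.000358, and adjusted p = 0.515 with an estimated correlation), among them the calprotectin gene S100a8 at 9.93 ± 0.91 against 26.5 ± 8.21 FPKM. Macrophages and uterine natural killer cells were also the 2 lists that passed fry, with adjusted p = 0.0183 and 0.0439. These 3 lists were called without any 1 of the 4 libraries. The neutrophil call was lost with no filter (mean -0.27 in place of -0.54, adjusted p = 0.0575, with a range of 0.000184 to 0.515 over the alternatives).

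Inflammatory, interferon, complement and antigen-presentation genes were lower on balance too. Lists can share members, as the complement and macrophage lists share C1qb and C1qc, so they are not separate evidence throughout. Of 19 cytokine and chemokine genes 14 were lower (camera adjusted p = 0.000676, and adjusted p = 0.542 with an estimated correlation), and 3 of them passed when adjusted over the list alone. These were Cxcl1 at 1.09 ± 0.16 against 3.29 ± 0.51 FPKM, Ccl2 at 0.94 ± 0.26 against 3.06 ± 0.87 FPKM and Il1b at 1.15 ± 0.17 against 2.42 ± 0.30 FPKM (SD, n = 2). Of 30 interferon-response genes 27 were lower, 0 of them adjusted over the list alone and 8 at an unadjusted p under 0.05 (camera adjusted p = 2.05e-05, and adjusted p = 0.495 with an estimated correlation), with the antiviral gene Bst2 at 81.0 ± 0.67 against 118 ± 15.2 FPKM. Of 30 complement and coagulation genes 22 were lower, 2 of them adjusted over the list alone (camera adjusted p = 0.00545, and adjusted p = 0.515 with an estimated correlation). The mean log2 fold change of this list was -0.21, and -0.11 without frozen replicate 1. Serpine1, which encodes the plasminogen activator inhibitor PAI-1, was 390 ± 119 against 1139 ± 5.19 FPKM. Of 19 antigen-presentation genes 13 were lower, 0 of them adjusted over the list alone and 5 at an unadjusted p under 0.05 (camera adjusted p = 0.0076, and adjusted p = 0.519 with an estimated correlation), among them Cd74 at 4.40 ± 1.19 against 7.93 ± 0.49 FPKM. The antigen-presentation call was lost without fresh replicate 2 (adjusted p = 0.12) and without frozen replicate 2 (adjusted p = 0.063), with a range of 0.00123 to 0.519 over the alternatives.

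The prolactin family was lower on balance after frozen transfer at the preset correlation of camera, while 3 placental cathepsins passed as higher over their list alone. Of 23 members of the prolactin family, hormones made by trophoblast and decidua, 21 were lower and 2 higher, and 2 of the lower ones passed when adjusted over the list alone, with a median log2 fold change of -0.85 (camera adjusted p = 1.96e-10, and adjusted p = 0.542 with an estimated correlation). Prl5a1 was 27.03 ± 14.1 against 99.8 ± 19.1 FPKM, Prl7a2 was 730 ± 4.02 against 1494 ± 262 FPKM and Prl2a1 was 917 ± 213 against 2258 ± 751 FPKM (SD, n = 2). The mean log2 fold change of this list was -0.88, and -0.47 without fresh replicate 2, in which Prl7b1 reached 292 FPKM against 24.5 to 40.0 FPKM in the others. The most abundant member, the placental lactogen Prl3b1, did not differ beyond its spread (9350 ± 1972 against 9116 ± 1776 FPKM). Of 21 pregnancy-specific glycoprotein and Ceacam genes 15 were lower, 0 of them adjusted over the list alone and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0164, and adjusted p = 0.851 with an estimated correlation), with Psg22 at 28.0 ± 24.0 against 104 ± 0.092 FPKM and Psg17 in the other direction at 337 ± 72.2 against 221 ± 66.5 FPKM. The mean of this list was -0.33, -0.52 without fresh replicate 1 and -0.15 without fresh replicate 2. The call was lost without fresh replicate 2 (adjusted p = 0.67), where the test pointed upward, and without frozen replicate 2 (adjusted p = 0.0502), with a range of 3.27e-07 to 0.851 over the alternatives. The placental cathepsin list had 8 tested members, 6 of them cathepsins, proteases specific to rodent placenta, and the others the trophoblast-specific proteins Tpbpa and Tpbpb. Of these 8, 3 passed when adjusted over the list alone, all of them cathepsins that were higher, and the list itself was not called (camera adjusted p = 0.641). Ctsq was 2945 ± 299 against 1142 ± 258 FPKM, Ctsr was 421 ± 87.1 against 211 ± 38.2 FPKM and Cts6 was 1293 ± 272 against 527 ± 196 FPKM, while Cts3 was 1056 ± 250 against 1695 ± 147 FPKM.

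**Figure D3:**
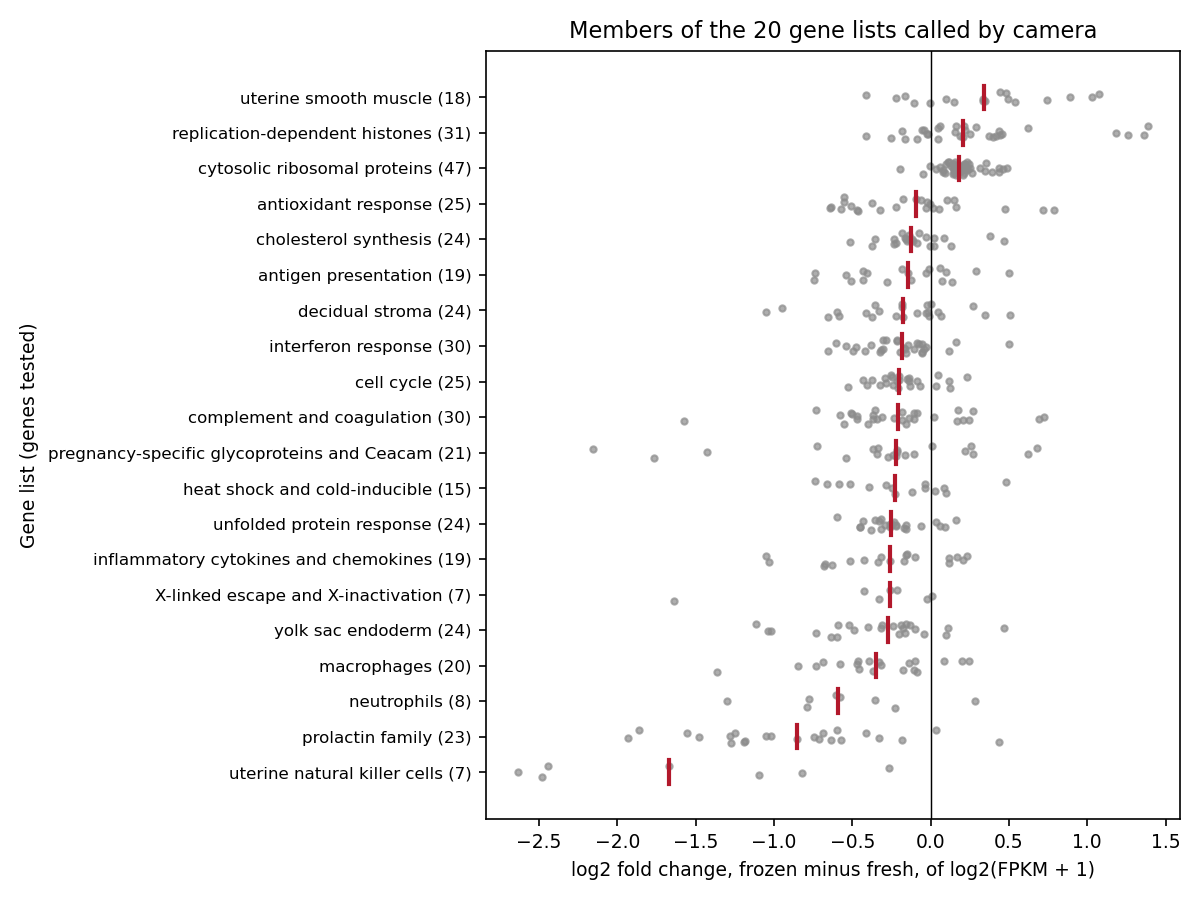
Log2 fold changes (frozen minus fresh) of the tested members of the 20 gene lists called by camera at its preset correlation; grey points are genes, red bars are list medians and numbers in parentheses are genes tested. Medians ran from -1.67 for uterine natural killer cells to 0.34 for uterine smooth muscle. With an estimated correlation, where the degrees of freedom come from the samples, 0 of the 20 lists were called.

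The unfolded protein response, heat shock, antioxidant and cell-cycle lists were lower on balance after frozen transfer, at the preset correlation of camera. Of 24 genes of the unfolded protein response 20 were lower (camera adjusted p = 8.81e-06, and adjusted p = 0.542 with an estimated correlation), 0 of them adjusted over the list alone and 6 at an unadjusted p under 0.05. Its members included the chaperone Hspa5 at 398 ± 35.8 against 542 ± 3.50 FPKM (SD, n = 2). Of 15 heat shock and cold-inducible genes 11 were lower (camera adjusted p = 0.00222, and adjusted p = 0.515 with an estimated correlation). Adjusted over the list alone, 5 passed as lower and 1 as higher: Hsph1 was 19.1 ± 3.45 against 32.3 ± 2.51 FPKM, while Cirbp, which is induced by cold, was the higher one at 18.97 ± 2.74 against 13.3 ± 1.34 FPKM. Of 25 antioxidant genes 17 were lower, 3 of them adjusted over the list alone (camera adjusted p = 0.00757, and adjusted p = 0.851 with an estimated correlation). The glutathione synthesis gene Gclc was 21.0 ± 0.66 against 33.4 ± 2.86 FPKM, Txnrd1 was 13.6 ± 0.31 against 20.7 ± 1.21 FPKM and the heme oxygenase gene Hmox1 was 39.5 ± 2.39 against 58.3 ± 2.04 FPKM. The mean of the antioxidant list was -0.13, -0.086 without frozen replicate 1, -0.014 without fresh replicate 1 and -0.25 without fresh replicate 2. Of 25 cell-cycle genes 20 were lower (camera adjusted p = 0.00191, and adjusted p = 0.851 with an estimated correlation), 0 of them adjusted over the list alone and 2 at an unadjusted p under 0.05, with the replication licensing gene Mcm6 at 5.98 ± 0.17 against 9.11 ± 1.21 FPKM. Their mean was -0.17, -0.077 without fresh replicate 1 and -0.27 without fresh replicate 2. The cholesterol synthesis list had 18 of 24 genes lower, 0 of them adjusted over the list alone and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0317, and adjusted p = 0.851 with an estimated correlation), and lost its call without fresh replicate 1 (mean -0.023, adjusted p = 0.22) and without frozen replicate 2 (mean -0.041, adjusted p = 0.45), as well as with no filter (adjusted p = 0.103), with a range of 0.00462 to 0.851 over the alternatives. Its mean was -0.091, -0.14 without frozen replicate 1 and -0.16 without fresh replicate 2.

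The lists that were higher after frozen transfer held ribosomal proteins, smooth muscle genes and histones. Of 47 cytosolic ribosomal protein genes 44 were higher by a small amount, with a median log2 fold change of 0.18, 0 of them adjusted over the list alone and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.00407, and adjusted p = 0.851 with an estimated correlation). Their mean was 0.19, -0.021 without fresh replicate 1 and 0.40 without fresh replicate 2. The call was lost without fresh replicate 1 and without frozen replicate 2 (adjusted p = 0.12 and 0.10), with a range of 1.89e-15 to 0.851 over the alternatives. Of 18 uterine smooth muscle genes 13 were higher, 0 of them adjusted over the list alone and 8 at an unadjusted p under 0.05 (camera adjusted p = 0.0184, and adjusted p = 0.851 with an estimated correlation), with Tagln at 19.7 ± 5.25 against 8.83 ± 2.42 FPKM and the smooth muscle actin gene Acta2 at 48.4 ± 15.6 against 23.1 ± 7.46 FPKM (SD, n = 2). Of 31 replication-dependent histone genes 22 were higher, 2 of them adjusted over the list alone (camera adjusted p = 0.0204, and adjusted p = 0.851 with an estimated correlation). Hist1h3c was 2.75 ± 0.59 against 0.46 ± 0.20 FPKM. Histone genes are near-identical in sequence and their values are uncertain. The smooth muscle and histone calls were lost without fresh replicate 2 (adjusted p = 0.20 and 0.26) and without frozen replicate 2 (adjusted p = 0.095 and 0.085), with ranges of 0.00231 to 0.851 and 0.0016 to 0.851 over the alternatives. The means were 0.34 and 0.29, 0.53 and 0.45 without fresh replicate 1 and 0.15 and 0.12 without fresh replicate 2, and the smooth muscle mean was 0.21 without frozen replicate 2.

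Several collagen, elastin and fibrillin genes passed as higher over their lists alone, while these lists were not called as a whole. Of 20 fetal mesenchyme and pericyte genes, 7 passed as higher and 1 as lower when adjusted over the list alone, and the list had a camera adjusted p of 0.0631. It was called, as higher, under 6 of 11 alternatives, among them median-of-ratios scaling (adjusted p = 0.0384), upper-quartile scaling (adjusted p = 0.0255), no filter (adjusted p = 0.0384), and the fits without frozen replicate 1 (adjusted p = 0.00724) and without fresh replicate 1 (adjusted p = 0.0337), with a range of 0.00724 to 0.851. The collagen genes Col6a1, at 11.2 ± 0.97 against 5.49 ± 0.81 FPKM, and Col3a1, at 104 ± 10.2 against 58.6 ± 11.9 FPKM (SD, n = 2), were higher, and Thy1 was lower at 0.86 ± 0.18 against 4.16 ± 1.57 FPKM. Of 29 matrix remodelling genes 3 passed as higher when adjusted over the list alone (camera adjusted p = 0.378), among them the elastin gene Eln at 11.9 ± 0.44 against 4.75 ± 0.78 FPKM and the fibrillin gene Fbn1 at 12.6 ± 0.52 against 7.49 ± 1.33 FPKM. The median (-0.083) and the mean (0.0054) of that list differ in sign, and its test pointed downward. Of 24 decidual stroma genes 18 were lower, with a median of -0.18 (camera adjusted p = 0.0184, and adjusted p = 0.851 with an estimated correlation), and Bmp2 alone passed when adjusted over the list alone, at 1.29 ± 0.20 against 3.42 ± 0.23 FPKM. That list lost its call without fresh replicate 1 (adjusted p = 0.69) and without frozen replicate 2 (adjusted p = 0.14), as well as with no filter (adjusted p = 0.0806), with a range of 8.41e-06 to 0.851 over the alternatives. Its mean was -0.21, 0.0044 without fresh replicate 1 and -0.42 without fresh replicate 2. Of 24 yolk sac endoderm genes 21 were lower, 0 of them adjusted over the list alone and 4 at an unadjusted p under 0.05 (camera adjusted p = 0.0051, and adjusted p = 0.851 with an estimated correlation), with the transferrin gene Trf at 68.5 ± 7.99 against 98.7 ± 14.04 FPKM. Their mean was -0.35, and it turned to 0.34 without frozen replicate 1, where the call was lost (adjusted p = 0.66), as it was without fresh replicate 2 (mean -0.098, adjusted p = 0.14) and with no filter (adjusted p = 0.0737), with a range of 2.95e-10 to 0.851 over the alternatives. It was -1.05 without frozen replicate 2 and -0.61 without fresh replicate 1.

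The imprinted lists were not called, and Plagl1 and Nnat were their only members to pass over the list alone. Igf2, the fetal growth factor, was 2014 ± 28.7 FPKM after frozen and 1264 ± 282 FPKM after fresh transfer (SD, n = 2), a log2 fold change of 0.69 ± 0.25 (SE, adjusted p = 0.334). Its neighbour H19, a maternally expressed lncRNA, was 2700 ± 272 against 2742 ± 46.1 FPKM. Of 27 paternally expressed genes 2 passed when adjusted over the list alone, Plagl1, a zinc finger regulator, at 122 ± 10.02 against 74.2 ± 2.14 FPKM and Nnat at 4.95 ± 1.56 against 1.60 ± 0.37 FPKM, and the list was not called (camera adjusted p = 0.739, with a mean of 0.04, a median of -0.014 and a downward test, and a mean of -0.011 under upper-quartile scaling). Of 29 maternally expressed genes 0 passed when adjusted over the list alone and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.73), with Grb10, an adaptor of insulin receptor signalling, at 116 ± 33.5 against 66.5 ± 8.34 FPKM and Meg3 at 66.5 ± 6.98 against 46.2 ± 6.68 FPKM. Differences were within the spread between placentas for Cdkn1c, Phlda2, Peg3, Mest, Dlk1, Airn, Peg10 and Ascl2, whose libraries overlapped between groups. Of 31 genes of IGF, insulin and mTOR signalling, 2 passed as higher when adjusted over the list alone (camera adjusted p = 0.206): Igfbp6 was 29.1 ± 7.53 against 11.8 ± 0.049 FPKM and Mtor was 22.5 ± 1.57 against 14.6 ± 0.26 FPKM.

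Among transport and steroid genes, single members stood out. The cationic amino acid transporter gene Slc7a1 was 96.7 ± 16.2 against 49.96 ± 2.52 FPKM (SD, n = 2) and was the 1 gene of 21 in the glucose and amino acid transport list that passed when adjusted over the list alone (camera adjusted p = 0.342). The glucose transporter gene Slc2a1 was 577 ± 94.3 against 445 ± 75.4 FPKM. Hsd11b1, whose enzyme regenerates active glucocorticoid, was 77.8 ± 10.6 against 17.5 ± 5.07 FPKM, a log2 fold change of 2.11 ± 0.22 (SE, adjusted p = 0.146), and was the 1 gene of 14 in the steroid list that passed when adjusted over the list alone (camera adjusted p = 0.879, with a positive mean and a downward test). The X-linked list had 6 of 7 genes lower, 0 of them adjusted over the list alone and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0191, and adjusted p = 0.851 with an estimated correlation), which was lost among the female placentas (adjusted p = 0.75), without fresh replicate 1 (adjusted p = 0.057) and without fresh replicate 2 (adjusted p = 0.058), with a range of 2.65e-05 to 0.851 over the alternatives. Its mean was -0.41, -0.01 among the female placentas and -0.81 without frozen replicate 2.

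For lncRNA genes, the question was which of them differ after frozen transfer. Gm2560 and BGIG10090_39217 were lower in both frozen placentas than in both fresh ones. Gm2560 (chromosome 4, 14212012 to 14291367) was listed at 0 in both frozen libraries and at 4.74 and 6.17 FPKM in the fresh libraries, and BGIG10090_39217 was 0.33 ± 0.071 against 5.95 ± 0.42 FPKM (SD, n = 2). Both had an adjusted p of 0.0177 over the 3135 lncRNA genes tested with limma-trend, and 0.0954 over all genes. They were the only 2 lncRNA genes to pass, with 0 higher, and 402 had an unadjusted p under 0.05, of which 210 were higher and 192 lower. The count was 0 without frozen replicate 1, without fresh replicate 1 or without fresh replicate 2, and 2 without frozen replicate 2, of which 1 was higher. It was also 0 without a filter. Tmem41b, whose pseudogene BGIG10090_39217 overlaps, differed in the opposite direction.

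Other lncRNA genes named by rule did not pass. B230312C02Rik (chromosome 2, 180370492 to 180439551) was 21.4 ± 5.79 against 4.88 ± 0.93 FPKM (SD, n = 2), Gm41094 was 1.97 ± 0.36 against 0.34 ± 0.064 FPKM and 5830444B04Rik was 7.05 ± 0.35 against 3.23 ± 0.39 FPKM. Hymai, which lies within the span of Plagl1 on chromosome 10, was 12.8 ± 0.64 against 7.80 ± 0.54 FPKM. In the other direction, BGIG10090_34922 was 4.73 ± 0.085 against 17.1 ± 3.53 FPKM, Gm33441 was 11.4 ± 1.27 against 21.9 ± 0.45 FPKM and Gm13269 was 0.86 ± 0.021 against 2.42 ± 0.085 FPKM. The list of 36 known lncRNAs was not called (camera adjusted p = 0.726, with a mean of 0.029, and of -0.019 under upper-quartile scaling), and Kcnq1ot1 was 11.0 ± 0.11 against 9.28 ± 0.52 FPKM.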

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

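The tests of this part were chosen after the data were seen. The circular RNA values of the deposited tables were not part of the comparisons above. Among them, 17 circular RNA regions on chromosome 9 between 3000178 and 3037421 (GRCm38) had a median of 1843 RPM in frozen replicate 1, against 208 RPM in frozen replicate 2, 476 RPM in fresh replicate 1 and 284 RPM in fresh replicate 2. They held 29.5% of all circular RNA RPM in frozen replicate 1 and 3.27 to 7.55% in the others. The level in this 1 library lay above that of the fresh placentas, while the other frozen library lay below it, so it does not follow the transfer groups. Over all circular RNA regions, 23 were above 50 RPM in frozen replicate 1 and over 3 times the highest other library. Of these 23 regions, 17 were those of this chromosome 9 cluster. No explanation was tested.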

How the results depend on the processing

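Upper-quartile scaling, the other pseudocount for the lists, the other lncRNA definitions and the adjustment over all genes were chosen after the data were seen. The count of genes at an adjusted p under 0.05 was 0 under both scalings, a pseudocount of 0.1, no filter, a mean of at least 5 FPKM and the replicate block. It was 2 without sex-linked, globin and mitochondrial genes and with the libraries rescaled. Without 1 library it was 0 to 2. The 2385 genes at an unadjusted p became 1444 with a mean of at least 5 FPKM, where fewer genes were tested, and 1271 to 2245 without 1 library. The 2 lncRNA calls were 2 under both scalings, a pseudocount of 0.1 and without sex-linked, globin and mitochondrial genes, 3 with gene types as printed, 1 with RefSeq types, 0 adjusted over all genes, 0 without a filter, 5 with a mean of at least 5 FPKM, where 422 lncRNA genes were tested, 0 with the replicate block and 0 to 2 without 1 library. The 20 lists became 0 with an estimated correlation, 2 with fry, 20 to 21 under both scalings, the other pseudocount and the replicate block, and 14 to 24 without 1 library. With no filter 20 were called, 7 higher and 13 lower, of which 16 were among the first 20; neutrophils, yolk sac endoderm, decidual stroma and cholesterol synthesis were lost and 4 others gained. For the 25 lists not called, 24 of 275 alternatives gave a call and 25 turned the direction of the test. Leaving out 1 library kept 11 of the 20 calls in all 4 fits. It assumes that the lone sample varies like the other group. Numbers did not pair the placentas (correlation of deviations -0.0185), and the replicate block gave 2046 genes at an unadjusted p.

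Of 2331 values for single genes under alternatives, 26 pointed the other way, all of genes that had not passed. Under median-of-ratios scaling Airn was -0.021, and under upper-quartile scaling Airn was -0.047 and Prl3b1 -0.021. Without sex-linked, globin and mitochondrial genes, and with the libraries rescaled, H19 was 0.0049. The other values that turned did so when 1 library was left out, with these lowest and highest log2 fold changes over the 4 fits: Xist -3.44 to 0.16, Cdkn1c -1.32 to 0.37, Ascl2 -0.27 to 0.44, Hbb-b2 -0.035 to 8.72, Gm12191 -0.12 to 5.12, Prl3b1 -0.18 to 0.25, Afp -3.43 to 1.39, Mest -0.23 to 0.38, H19 -0.13 to 0.077, Airn -0.11 to 0.13, Prl8a2 -0.67 to 0.31, Dlk1 -0.46 to 0.12, Plin4 -0.46 to 0.0901, Peg10 -0.15 to 0.36, Prl7b1 -3.04 to 0.48 and Prl2c1 -3.84 to 0.12. Among the called lists, the means that turned were yolk sac endoderm, at -1.05 to 0.34, cytosolic ribosomal proteins, at -0.021 to 0.40, and decidual stroma, at -0.42 to 0.0044, where the test still pointed downward. For pregnancy-specific glycoproteins the direction of the test turned without fresh replicate 2, while the means were -0.52 to -0.15. The cause was not tested. Count-based fits (upper-quartile factors in a count model, a Wald test on counts) and isoforms were not run, since the tables hold FPKM per gene. The unknown depth limits what low FPKM values show.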

Other observations

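The tests on gene copies, granzymes, prolactins, circular RNAs and genes high in 1 placenta were chosen after the results were seen, while the list tests were planned. In 2 trophoblast lists that were not called, 3 genes passed as higher over their list alone. The trophoblast giant cell list was not called either (camera adjusted p = 0.0705), and Ctsq passed as higher over that list alone. The mean log2 fold change of the giant cell list was -0.36, -0.58 without frozen replicate 1 and -0.14 without frozen replicate 2. That list was called under 2 of 11 alternatives. Of its 14 tested genes 9 were lower and 5 higher. The lower ones included Prl2a1, Prl3d1 and Prl2c2, which also belong to the prolactin family list. In the labyrinth syncytiotrophoblast list, the homeobox gene Dlx3 was 39.7 ± 4.21 FPKM after frozen and 17.9 ± 6.24 FPKM after fresh transfer (SD, n = 2), and Snap91 was 26.8 ± 0.74 against 11.9 ± 3.68 FPKM. Both passed when adjusted over the list alone and neither over all genes. Gcm1, a regulator of syncytiotrophoblast differentiation, did not pass, at 3.42 ± 0.61 against 8.995 ± 5.61 FPKM. The list was not called by camera (adjusted p = 0.894). In the trophoblast progenitor list, Tfap2a passed when adjusted over the list alone, at 11.9 ± 0.35 against 6.01 ± 0.69 FPKM, while the keratin genes Krt8 and Krt18, which did not pass, were 532 ± 88.4 against 755 ± 21.8 FPKM and 537 ± 83.7 against 752 ± 29.5 FPKM, and the list was not called (adjusted p = 0.831). Of 33 DNA methylation and histone modifier genes 24 were higher (camera adjusted p = 0.107), and the list was called with no filter (adjusted p = 0.00562) and without frozen replicate 1 (adjusted p = 0.0268), with a range of 0.00562 to 0.851 over the alternatives. Of 40 nuclear oxidative phosphorylation genes 30 were higher (camera adjusted p = 0.11), and the list was called with no filter (adjusted p = 0.00441), without frozen replicate 1 (adjusted p = 0.00564) and without fresh replicate 2 (adjusted p = 0.00932), with a range of 0.00441 to 0.958.

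The globin copies Hbb-b1 and Hbb-b2 were 1894 and 432 FPKM in frozen replicate 1 and at most 0.13 FPKM in the others, and Gm12191 was 96.7 FPKM there and 1.59 to 1.96 FPKM elsewhere. The annotation places both globin copies on a separate scaffold and not on a chromosome. In fresh replicate 2, Prl2c1 was 110 FPKM against 6.11 to 7.07 FPKM. The fetoprotein gene Afp was high in 1 placenta of each group, at 3.55 and 127 FPKM in the frozen libraries and 19.96 and 113 FPKM in the fresh ones. Globin genes held 2.03 to 7.65% of the summed FPKM per library.

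Across 1038 host mRNA genes with circular RNA regions of at least 5 RPM on average, the log2 change of the circular RNAs and that of the host gene had a Pearson r of 0.748 and a Spearman rho of 0.713. The other 2 splits of the libraries into pairs gave an r of 0.553 and 0.626 and a rho of 0.481 and 0.569, so a positive relation was not specific to the transfer groups. It is a relation across genes, which are not independent replicates. Of the lists with too few tested genes, the embryonic globins Hba-x and Hbb-y were 0.12 and 0.05 against 1.24 and 2.83 FPKM, and 0.17 and 0 against 0.47 and 1.47 FPKM.

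The 3 splits of the 4 libraries into pairs are too few to give a share under 0.05. The real split gave 2385 genes at an unadjusted p under 0.05 and the highest other gave 537, so that 1 of the 3 splits, the real one, gave as many.

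Named genes with a related copy on another chromosome were Ahcy, Rpl26 and BGIG10090_39217. If reads were divided between near-identical copies, a change of the gene would come with an opposite change of the copy. The median change of the copy per FPKM of change in the gene was -0.384 over all 6 pairs that shared an alias or a pseudogene, and -0.804 over these 3, which were set apart from granzyme paralogs and 1 pair of unrelated proteins after the first value was seen. The second median therefore decides nothing, and divided reads stay open. Sequence variants that differ between ICR animals stay open too: Hbb-b1 was 1894 FPKM in 1 placenta and under 1 FPKM in the other 3, but no genotypes were tested, and an effect of the transfer on either copy cannot be told apart from them.

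The 5 tested granzyme genes, Gzmc to Gzmg, were lower in both frozen placentas, while Gzma, too low to test, was not, at 0.11 and 0.21 against 0.11 and 0.14 FPKM. An even loss of decidua from the dissected placentas would lower decidual stroma markers by about as much. Their median log2 change was -0.178 with an SD of 0.375 over 24 genes, against -1.67 for the uterine natural killer list. Of the 24 genes 18 were lower and 6 higher, with Bmp2 at -0.95 and Prl3c1 at -1.05 but Alpl at 0.50. Stroma markers cannot show whether the part of the decidua that holds natural killer cells was dissected alike, so less of that part stays open. Reads divided between granzyme paralogs would move paralogs apart. The median was 0.552 FPKM per FPKM of change over 2 pairs, 0.886 for Gzmg with Gzmf and 0.219 for Gzmd with Gzmc. These genes were already seen to be lower, so the sign was fixed in advance and the ratio adds no separate support. Their values do show that the sum of Gzmg and Gzmf was lower too, at 1.11 and 0.24 against 14.84 and 12.42 FPKM, which a division within that pair would not give. Fetal sex stays open: in the comparison of female placentas the list median was -1.49, which rests on 1 frozen library. A difference in granzyme-expressing cells with the type of transfer remains an untested hypothesis, and Prf1, at 0.04 and 0.03 against 0.60 and 0.65 FPKM, was too low to test.

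The prolactin family was lower on balance after frozen transfer at the preset correlation of camera, a call that was lost with fry (adjusted p = 0.491) and at adjusted p = 0.542 with an estimated correlation, with a range of 2.67e-19 to 0.542 over the alternatives. Fewer spongiotrophoblast and giant cells together would lower the other markers of these cells alike. The median log2 change of 22 other markers was 0.052 with an SD of 0.533, against -0.854 for the prolactin family. Of these markers 12 were higher and 10 lower, with Ctsq at 1.38 and Cts6 at 1.33 but Hand1 at -0.45, Rhox6 at -0.35 and Tpbpa at -0.24. The median pools markers of several cell types, so it cannot decide whether 1 of these types was fewer. A difference in gestational stage stays open, since the labels give no day: Prl3d1 and the embryonic globins, genes of early placenta, were lower, and the later placental lactogen Prl3b1 differed by 0.034 with an SE of 0.51, which decides nothing. The type of transfer itself remains among the open explanations.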
